A study of Mus musculus with 12 samples.

How the data were processed

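Messenger RNA was sequenced from cultured cells of 2 mouse mammary tumour lines, 4T1 and EMT6. Each line was given as control cells and as knockout cells (KO) labelled sgNEDD4, the usual notation for a guide RNA against Nedd4, with 3 libraries per group, 4 groups and 12 libraries. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum, total RNA was extracted, and libraries were made with a kit that captures mRNA on beads. All libraries carry the same batch label. Whether the 3 libraries of a group came from separate cultures or clones, and where the guide lies in Nedd4, is not given in the sources used here.

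Per the submitters' processing notes, the authors used cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1, DESeq2 (no version stated) and the genome GRCm38, and the role of each tool is not given in the sources used here. The deposited table of each line lists 56691 genes, with raw read counts and FPKM (counts scaled by exonic gene size and library total) for the 6 libraries. Control columns are headed WT per the file headers. The deposited FPKM were checked against the counts: FPKM computed from count, total count and the deposited exonic gene size matched within 0.005 for all 340146 values of each line. The tables' gene coordinates are not those of GENCODE M21, an annotation of GRCm38. Of the 52073 gene identifiers in both, 99.996% lay on the same chromosome and 96.8% had the same span length, but 2.83% had the same start and end. Coordinates are therefore given only as the tables print them, without a build. M21 was used for GC content, for gene biotypes and to look up listed symbols that the tables do not use. The strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes that overlap another gene or have near-identical copies are uncertain.

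Total counts per library ran from 13705612 to 19761604, so 3 counts correspond to 0.152 to 0.219 CPM (counts scaled to the library total). Intervals and limits from counts cover counting error only, since reads without molecular identifiers are not independent molecules. Between libraries of a group, the chi-square per degree of freedom of the counts was 2.45 to 11.8, the lowest correlation of log2 CPM across genes was 0.991, and no pair was identical.

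Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately in each line. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and KO was compared with control by edgeR's quasi-likelihood test with robust dispersion. P-values were adjusted over all tested genes of a line by Benjamini-Hochberg, and a gene is called where the adjusted p is under 0.05. All tests are 2-sided except Fisher's exact tests of overlap, which are 1-sided. Gene fold changes are log2 of KO over control with the standard error (SE) of the fit, and FPKM are means with standard deviations (SD) over 3 libraries. The biological coefficient of variation was 4.82% in 4T1 and 6.73% in EMT6. These p-values measure only the spread between the sequenced libraries. The difference between the lines was tested as the interaction of line and knockout in a fit of all 12 libraries, over genes that passed the filter in both lines. The level of a gene in one line was not compared with its level in the other.

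A total of 35 gene lists, the comparisons, the tests and most alternatives were fixed before the data were examined. Of the listed symbols, all but H2-L were found, by the tables' own symbols or through M21 by gene identifier. The 32 lists with at least 5 tested members in a line were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the lists of a line. Camera compares a list with all other genes. Its version with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it. Chromosomes were tested with camera as sets of genes.

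Named genes followed a rule fixed in advance. It takes Nedd4 and its ligase family, and per line the 6 largest increases and 6 largest decreases among called genes with a mean of at least 1 FPKM, with all KO libraries on one side of all controls, and without clone or predicted-gene symbols. It adds up to 4 members with the lowest adjusted p from at most 10 lists per line, taken by lowest camera p among lists that were called or had at least 3 called members of which at least 80% went one way. It also takes the 6 genes called higher and the 6 called lower in both lines whose smaller change was largest, the 6 genes with the lowest interaction p among those called in opposite directions, and at most 4 markers of other cell types with at least 5 FPKM in a group. The results of 2 genes that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

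The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, scaling by total counts only, no low-count filter, a mean count of at least 50, limma on log2 FPKM with other pseudocounts (1, 0.1 and 0.01) and other filters, a fit of all 12 libraries, leaving out each library in turn, replicate number as a block, and stricter thresholds. Others were added after seeing the data: libraries thinned to equal totals, edgeR on genes with a mean of at least 5 FPKM, centring each chromosome's genes, and removing a trend on GC content and gene length. GC content was computed with Biostrings 2.70.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

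The procedure was tested on simulated data in which every gene had the biological coefficient of variation of its line. Of 12872 genes tested, 95 and 92 were changed by log2 0.5 and 1 in the 4T1 simulation, and 100 and 96 in that of EMT6. The shares of false calls below therefore do not cover data in which most genes change or in which the spread differs by gene. With changes planted at log2 0.5 and 1, edgeR called 82.1% and 94.6% of the changed genes with the 4T1 libraries and 79.0% and 96.9% with the EMT6 libraries, and 4.62% and 4.97% of its calls were false. For the difference between lines these shares were 61.5% and 85.4%, with 2.27% of calls false. A list of 40 genes shifted by 0.3 was called in both lines, and 0 of 30 lists left alone were called by camera. The simulated genes varied independently and the lists were drawn at random. The simulation therefore cannot test the preset correlation, on which the list calls in the real data depend. Every library and every table was used. The annotation columns of pathways were used only for an added test among the other observations.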

Results

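The data are RNA-seq read counts from 12 libraries of 2 mouse mammary carcinoma lines that grow as transplantable tumours in BALB/c mice. In 4T1, a line known for spontaneous metastasis, the control libraries held 16151320, 14975532 and 13705612 counts. The KO libraries held 16925883, 16405298 and 17613842. In EMT6, the control libraries held 14307493, 18285495 and 19203524 counts, and the KO libraries 19409819, 19761604 and 15742456. Each group has n = 3 libraries. The labels imply 3 comparisons: KO with control in 4T1, KO with control in EMT6, and the KO effect of EMT6 with that of 4T1. They ask which transcripts differ in cells in which Nedd4 was targeted, and whether both lines respond alike.

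Nedd4, a HECT-type E3 ubiquitin ligase, was lower in every KO library than in every control library. In 4T1, Nedd4 stood at 94.4, 97.6 and 93.5 FPKM in the controls and at 24.7, 24.9 and 25.3 FPKM in the KO libraries. Its mean fell from 95.2 ± 2.14 to 25 ± 0.296 FPKM (SD, n = 3), which left 26.3% of the control level. In EMT6, Nedd4 stood at 122.5, 121.4 and 116.5 FPKM in the controls and at 12.1, 11.5 and 12.1 FPKM in the KO libraries. Its mean fell from 120 ± 3.19 to 11.9 ± 0.365 FPKM, which left 9.89%. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 change was -2.01 ± 0.04 (SE, adjusted p = 6.19e-21) in 4T1 and -3.34 ± 0.06 (adjusted p = 5.6e-16) in EMT6. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. The gene is ENSMUSG00000032216, protein-coding in GENCODE M21. The deposited tables place it on chromosome 9 at 72569628 to 72657134 on the plus strand, with 12601 bases of exons. Their coordinates do not match the annotation of the build named in the processing notes. The counts cover the whole gene, so the position of the remaining reads along Nedd4 was not analysed here.

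**Figure D1:**
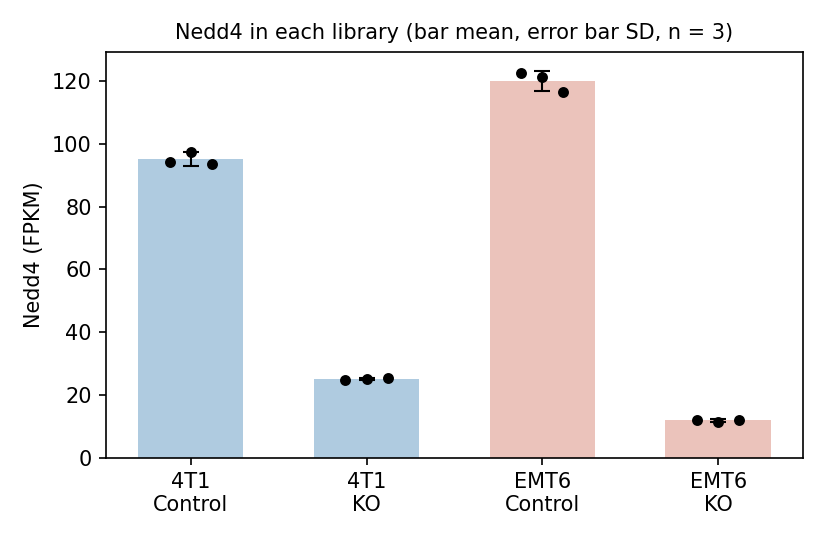
Nedd4 level in FPKM for control and KO cells of 4T1 and EMT6, with bars at the mean, error bars of 1 SD and a point for each of the 3 libraries. The KO means are 25 FPKM in 4T1 and 11.9 FPKM in EMT6, against 95.2 and 120 FPKM in the controls.

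Relatives of Nedd4 moved up and down in each line. In 4T1, 3 of 13 tested NEDD4-family ligases and adaptors were called higher and 5 lower (9 called when adjusted over the list alone). Nedd4l, the closest paralog, rose from 2.11 ± 0.162 to 3.07 ± 0.171 FPKM in 4T1 (log2 change 0.46 ± 0.07), while Arrdc3, an arrestin-domain adaptor, fell by 0.63 ± 0.07 and Ndfip2 and Ndfip1, membrane activators of these ligases, fell by 0.30 ± 0.06 and 0.20 ± 0.05. Another adaptor, Arrdc4, rose in 4T1 from 1 to 6 counts per control library to 36 to 53 per KO library. In EMT6, 3 of 11 were called higher and 2 lower (5 when adjusted over the list alone). There Itch and Wwp2, both ligases of the family, rose by 0.42 ± 0.06 and 0.44 ± 0.05, and Nedd4l fell by 0.36 ± 0.07. The Nedd4l change differed between the lines by -0.84 (edgeR, adjusted p = 7.34e-08). Ndfip2 also fell in EMT6, by 0.20 ± 0.06, a call lost on leaving out a library, and its change did not differ between the lines (edgeR, adjusted p = 0.457). The family as a list was not called in 4T1 (camera, adjusted p = 0.757, median -0.03 but mean 0.20) or in EMT6 (camera, adjusted p = 0.732).

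In 4T1 cells, MYC and ribosome biogenesis targets fell and most G2/M genes rose. All 40 tested MYC and ribosome biogenesis targets were called lower in KO (40 when adjusted over the list alone, median -0.57). Among them, Odc1, the rate-limiting enzyme of polyamine synthesis, fell from 248 ± 9.45 to 129 ± 1.23 FPKM (log2 change -1.02 ± 0.04, SE, n = 3 per group). Nop56, a core protein of the particles that methylate ribosomal RNA, fell by 0.87 ± 0.05, the RNA helicase Ddx21 by 0.76 ± 0.05, and the nucleolar protein Npm1 by 0.71 ± 0.04. Of 45 G2/M genes, 39 were called higher and 0 lower (39 when adjusted over the list alone, median 0.30), with Cdc25b, a phosphatase that drives entry into mitosis, at 0.67 ± 0.05, Espl1 (separase) at 0.61 ± 0.05, the chromokinesin Kif4 at 0.60 ± 0.05 and the centromeric histone Cenpa at 0.53 ± 0.05. Camera called both lists, with adjusted p = 6.41e-14 for the ribosome biogenesis list and 4.45e-09 for the G2/M list. With an estimated correlation neither was called, at adjusted p = 0.297 for each.

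Genes of the ATF4 and NRF2 lists of 4T1 rose more often than they fell. Of 29 ATF4 and integrated stress response genes, 22 were called higher and 2 lower (26 when adjusted over the list alone). The median was 0.46 (camera adjusted p = 3.47e-05, adjusted p = 0.677 with an estimated correlation). Asns, which makes asparagine, rose from 54.9 ± 3.79 to 99.7 ± 5.37 FPKM, Slc7a11, the cystine importer, from 0.437 ± 0.0416 to 1.30 ± 0.133 FPKM, and Pycr1, of proline synthesis, from 2.60 ± 0.151 to 5.99 ± 0.33 FPKM. Against the list, the tryptophanyl-tRNA synthetase Wars fell by 0.66 ± 0.05. Of 28 NRF2 targets and glutathione genes, 17 were called higher and 4 lower (21 when adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0362, adjusted p = 0.677 with an estimated correlation). Malic enzyme Me1 rose by 0.60 ± 0.06, glutathione transferase Gstm2 by 1.27 ± 0.13 and ferritin light chain Ftl1 by 0.47 ± 0.05, and reads of Gstm2 and Ftl1 may be shared with close copies. The NRF2 call was lost without control replicate 2 (camera adjusted p = 0.0745) and without KO replicate 3 (camera adjusted p = 0.0702), with chromosome centring (camera adjusted p = 0.0848) and with no low-count filter (camera adjusted p = 0.0896).

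Immediate early, glycolysis, ER chaperone and epithelial genes of 4T1 fell more often than they rose. Of 35 immediate early genes, 22 were called lower and 5 higher (30 when adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.00143, adjusted p = 0.331 with an estimated correlation). Dusp6, a phosphatase induced by and acting on ERK, fell from 77.1 ± 2.38 to 39.0 ± 1.53 FPKM, and Dusp5, Ier3 and the prostaglandin synthase Ptgs2 fell by 0.94 ± 0.06, 0.70 ± 0.05 and 0.68 ± 0.04. Of 33 hypoxia and glycolysis genes, 18 were called lower and 1 higher (19 when adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00448, adjusted p = 0.824 with an estimated correlation). Lactate dehydrogenase Ldha stood at -0.66 ± 0.05, the glucose transporter Slc2a1 at -0.85 ± 0.07, and the glycolytic enzymes Pfkl and Tpi1 at -0.74 ± 0.06 and -0.59 ± 0.05. Of 23 ER chaperones, 17 were called lower and 2 higher (19 when adjusted over the list alone). The median was -0.31 (camera adjusted p = 0.00563, adjusted p = 0.297 with an estimated correlation). Hspa5 (BiP) stood at -0.52 ± 0.04, Manf at -0.56 ± 0.04, Dnajc3 at -0.54 ± 0.05 and Calr at -0.44 ± 0.05. Of 27 epithelial genes, 15 were called lower and 5 higher (20 when adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0309, adjusted p = 0.323 with an estimated correlation). Epcam, an adhesion molecule of epithelia, fell from 149 ± 5.16 to 72.0 ± 2.42 FPKM, keratin Krt8 from 655 ± 9.28 to 399 ± 8.50 FPKM, and the tight junction genes Ocln and Cldn4 by 0.74 ± 0.06 and 0.65 ± 0.06. The epithelial call was lost without control replicate 3 (camera adjusted p = 0.0513) and among genes with a mean of at least 5 FPKM (camera adjusted p = 0.149). Of 50 oxidative phosphorylation genes, 20 were called lower and 4 higher (22 when adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.0134, adjusted p = 0.824 with an estimated correlation). Subunits of the respiratory chain stood lower, Ndufb9 at -0.54 ± 0.05, Ndufa10 at -0.37 ± 0.05 and Uqcrc1 at -0.39 ± 0.05. That call was lost with scaling by total counts only (camera adjusted p = 0.0578) and among genes with a mean of at least 5 FPKM (camera adjusted p = 0.275).

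Among 4T1 genes with a mean of at least 1 FPKM over the 6 libraries, the largest increase of named genes was that of Amigo2, an adhesion molecule, which rose from 0.740 ± 0.201 to 9.77 ± 0.8 FPKM (12.7-fold). Next came Serpinb2, Klhl30 and Misp3, which rose by 3.59 ± 0.29, 3.49 ± 0.26 and 3.40 ± 0.30. Rhox5, an X-linked homeobox gene of the reproductive tract, followed, from 1.48 ± 0.47 to 12.3 ± 0.458 FPKM, and then Epb41l4a (2.87 ± 0.15). With the same limit, the 6 largest decreases included Nlrp10 (-5.29 ± 0.28), Miga1 (-4.45 ± 0.15), Epop (-3.88 ± 0.37), the transcription factor Sox15 (-3.85 ± 0.26, from 7.85 ± 0.996 to 0.567 ± 0.188 FPKM) and the collagenase Mmp1a (-3.78 ± 0.39). Bmyc, a MYC-related gene and also of the 6, fell from 37 to 42 counts per control library to 0 to 3 per KO library.

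In 4T1, 23 further lists were tested and not called by camera. YAP/TEAD targets came nearest, with 11 higher and 2 lower of 20 (13 when adjusted over the list alone, camera adjusted p = 0.054). Crim1, Arhgef17 and Gadd45b rose by 0.64 ± 0.05, 0.68 ± 0.05 and 0.69 ± 0.07, and the ecto-nucleotidase Nt5e fell by 0.66 ± 0.04. The others, by higher and lower members, were cholesterol synthesis with 11 and 4 of 24, G1/S and DNA replication with 5 and 22 of 44, heat shock with 2 and 10 of 16, FOXO targets with 9 and 2 of 22, mitochondrially encoded genes with 0 and 3 of 13, Wnt targets with 1 and 6 of 9, and fatty acid synthesis with 9 and 3 of 18. Autophagy and lysosome genes had 15 and 8 of 34, apoptosis and pyroptosis 5 and 9 of 23, Notch targets 2 and 3 of 8, interferon-stimulated genes 6 and 4 of 34, MHC class I 7 and 6 of 21, chemokines and cytokines 8 and 10 of 23, and TGF-beta targets 8 and 6 of 19. Ferroptosis regulators had 7 and 10 of 21, growth factors and receptors 10 and 4 of 21, checkpoint ligands 3 and 2 of 9, ribosomal proteins 15 and 13 of 50, NF-kappaB targets 8 and 8 of 22, mesenchymal genes 9 and 7 of 22, and p53 targets 8 and 9 of 26. When adjusted over the list alone, the counts of these 21 lists together with the ligase family ran from 3 (mitochondrially encoded genes) to 28 (ribosomal proteins). Their camera adjusted p-values ran from 0.0774 (cholesterol synthesis) to 0.983. The signs of median, mean and camera differed for chemokines (0.05, -0.05, down), NF-kappaB targets (-0.01, 0.18, down), Notch targets (-0.06, 0.07, down), p53 targets (-0.01, 0.06, down), ferroptosis regulators (-0.03, 0.03, down) and ribosomal proteins, whose mean was above 0 with the median below it and a camera direction of down.

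Markers of other cell types were few in 4T1. The 4 tested leukocyte markers included Cd68, a lysosomal protein of macrophages, which rose from 11.5 ± 1.02 to 18.6 ± 2.03 FPKM, and Cd14, which fell from 13.0 ± 0.648 to 8.13 ± 0.232 FPKM. Of 4 tested endothelial and fibroblast markers 0 were called by edgeR, with Eng at 19.6 ± 0.771 and 21.9 ± 1.76 FPKM and Pdgfra at 5.25 ± 0.489 and 5.17 ± 0.105 FPKM in control and KO. Of 3 tested histone genes, 2 were called higher. The 4T1 KO libraries also held more genes with a count, 20937 to 21264 against 18836 to 19017 in controls, and more of the nuclear RNAs Malat1 (479 to 560 against 69.3 to 155 CPM) and Neat1 (241 to 333 against 51.6 to 84.6 CPM).

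In all, edgeR called 7589 of 13313 tested genes in 4T1 (57.0%, and 8144 at an unadjusted p under 0.05), 3725 higher and 3864 lower. KO and control libraries did not overlap for 61.9% of the genes, against 10% by chance. The even split depends on the scaling and the genes kept: 49.1% of called genes were higher, against 61.2% with scaling by total counts only, 62.3% with unfiltered FPKM and 74.3% among genes with a change of at least 1 on the log2 scale (756 higher and 262 lower of 1018). Among protein-coding genes 3226 were higher and 3592 lower, and among other biotypes 499 higher and 272 lower.

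In EMT6 cells, interferon-stimulated and cholesterol synthesis genes rose. Of 41 tested interferon-stimulated genes, 37 were called higher in KO and 0 lower (38 called when adjusted over the list alone, median 1.04). Ifit1, an antiviral RNA-binding protein, rose from 1.33 ± 0.273 to 12.5 ± 1.27 FPKM (log2 change 3.21 ± 0.14, SE, n = 3 per group), Rtp4 from 3.19 ± 0.202 to 21.9 ± 2.38 FPKM, the guanylate-binding protein Gbp3 from 8.47 ± 0.561 to 33.0 ± 2.94 FPKM, and Cmpk2 by 2.42 ± 0.10. Of 25 cholesterol synthesis genes (SREBP2 targets), 24 were called higher and 0 lower (24 when adjusted over the list alone, median 1.14), with Cyp51, a lanosterol demethylase, up from 51.9 ± 4.89 to 145 ± 4.28 FPKM, and Lss, Mvk and Fdps up by 1.39 ± 0.07, 1.37 ± 0.09 and 1.09 ± 0.07. Camera called both lists, with adjusted p = 7.57e-15 for interferon-stimulated genes and 1.84e-10 for cholesterol synthesis. With an estimated correlation neither was called, at adjusted p = 0.337 and adjusted p = 0.603.

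Lipid, antigen presentation and matrix genes of EMT6 rose more often than they fell. Of 18 fatty acid synthesis and desaturation genes, 15 were called higher and 0 lower (15 when adjusted over the list alone). The median was 0.52 (camera adjusted p = 4.95e-05, adjusted p = 0.603 with an estimated correlation). The desaturase Scd2 rose from 360 ± 39.6 to 729 ± 37.3 FPKM, acetyl-CoA synthetase Acss2 by 1.12 ± 0.06, and Elovl1 and Acsl3 by 0.66 ± 0.06 and 0.55 ± 0.05. Of 21 MHC class I antigen presentation genes, 13 were called higher and 2 lower (15 when adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.00374, adjusted p = 0.603 with an estimated correlation). Tapbp (tapasin) rose from 66.9 ± 4.45 to 157 ± 2.55 FPKM, the peptide-trimming enzyme Erap1 by 1.13 ± 0.06, Tapbpl by 0.93 ± 0.09 and the class I gene H2-Q4, whose reads may be shared with related H2 genes, by 0.64 ± 0.06. Of 27 mesenchymal and matrix genes, 21 were called higher and 2 lower (23 when adjusted over the list alone). The median was 0.50 (camera adjusted p = 5.60e-05, adjusted p = 0.337 with an estimated correlation). Col3a1, a fibrillar collagen, rose from 0.0467 ± 0.0153 to 6.77 ± 0.352 FPKM, the PDGF receptor Pdgfrb from 0.953 ± 0.25 to 9.78 ± 0.16 FPKM and Timp1 from 69.6 ± 6.62 to 179 ± 4.67 FPKM, while the collagen crosslinker Loxl2 fell by 1.03 ± 0.08. Of 20 TGF-beta/SMAD targets, 15 were called higher and 3 lower (18 when adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.00852, adjusted p = 0.689 with an estimated correlation). Smooth-muscle actin Acta2 rose from 18.3 ± 2.81 to 343 ± 10.8 FPKM, Pmepa1 by 3.35 ± 0.15 and Id2 by 1.18 ± 0.08, and the matrix protein Ltbp2 fell by 2.89 ± 0.13.

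Epithelial, p53, ATF4, ribosomal and checkpoint-ligand genes of EMT6 fell more often than they rose. Of 17 epithelial genes, 13 were called lower and 2 higher (15 when adjusted over the list alone). The median was -1.23 (camera adjusted p = 9.09e-05, adjusted p = 0.337 with an estimated correlation). The cadherin Cdh3 fell from 7.47 ± 0.338 to 0.177 ± 0.0231 FPKM, desmoplakin (Dsp) from 20.2 ± 1.24 to 6.76 ± 0.386 FPKM and the transcription factor Elf3 fell by 2.65 ± 0.12, while Perp, a desmosomal protein and p53 target, rose from 0.167 ± 0.0751 to 7.28 ± 0.584 FPKM. Of 28 p53 targets, 19 were called lower and 3 higher (22 when adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.00158, adjusted p = 0.385 with an estimated correlation). The cell-cycle inhibitor Cdkn1a fell by 0.94 ± 0.06, Zmat3 by 0.95 ± 0.08 and Ccng1 by 0.80 ± 0.05. Of 28 ATF4 and stress response genes, 18 were called lower and 1 higher (20 when adjusted over the list alone). The median was -0.43 (camera adjusted p = 0.00158, adjusted p = 0.879 with an estimated correlation). Slc7a11 fell from 62.6 ± 5.18 to 17.7 ± 2.09 FPKM, its partner Slc3a2 by 0.77 ± 0.08, the mTORC1 inhibitor Ddit4 by 0.97 ± 0.06 and Atf4 itself by 0.48 ± 0.08. Of 50 cytosolic ribosomal proteins, 25 were called lower and 3 higher (28 when adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.00611, adjusted p = 0.603 with an estimated correlation). Rpl23, Rpl4 and Rpl17 fell by 0.57 ± 0.05, 0.49 ± 0.06 and 0.79 ± 0.10, and such genes have processed copies that may share reads. Of 12 checkpoint ligands, 9 were called lower and 1 higher (11 when adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.0396, adjusted p = 0.385 with an estimated correlation). Chosen after their values were seen, Nectin2, a ligand of TIGIT and CD226, fell from 15.9 to 3.96 FPKM, and Raet1d, an NKG2D ligand with close relatives that may share reads, fell by 2.71 ± 0.50. The checkpoint call was lost without control replicate 1 or KO replicate 3 (camera adjusted p = 0.0515 for each) and among genes with a mean of at least 5 FPKM (camera adjusted p = 0.179).

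Among EMT6 genes with a mean of at least 1 FPKM over the 6 libraries, the 6 largest decreases of named genes included the iron-binding secreted protein Lcn2 (-8.63 ± 0.19, from 78.4 ± 13.2 to 0.197 ± 0.0404 FPKM), inducible nitric oxide synthase Nos2 (-6.62 ± 0.28, from 52.9 ± 5.6 to 0.540 ± 0.279 FPKM), the granulocyte growth factor Csf3 (-6.59 ± 0.25, from 14.1 ± 1.17 to 0.137 ± 0.112 FPKM) and Smpd3 (-6.01 ± 0.29). Also of the 6, Pcdh7 fell from 395 to 509 counts per control library to 1 to 3 per KO library, and the cytokine Il36g from 104 to 174 counts to 0 to 2. With the same limit, the largest increases were Inmt, with 0 to 1 counts per control library against 112 to 126 per KO library, Col3a1 (7.09 ± 0.15), Perp (5.41 ± 0.23), Cdhr1 (5.21 ± 0.11), the lectin Lgals7 (4.61 ± 0.22) and Ifit3b (4.29 ± 0.35), which shares most of its sequence with Ifit3.

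In EMT6, 20 further lists besides the ligase family were tested and not called by camera. By higher and lower members, oxidative phosphorylation had 23 and 7 of 50, hypoxia and glycolysis 16 and 6 of 35, ER chaperones 13 and 5 of 23, MYC and ribosome biogenesis 9 and 14 of 40, chemokines and cytokines 5 and 9 of 21, growth factors and receptors 5 and 12 of 22, G2/M 18 and 10 of 45, and ferroptosis regulators 7 and 11 of 21. Notch targets had 2 and 5 of 9, YAP/TEAD targets 6 and 9 of 21, G1/S and DNA replication 18 and 11 of 44, NF-kappaB targets 7 and 9 of 19, NRF2 and glutathione 10 and 13 of 27, autophagy and lysosome 13 and 8 of 34, and Wnt targets 2 and 4 of 9. FOXO targets had 6 and 9 of 24, heat shock genes 4 and 4 of 17, immediate early genes 9 and 8 of 34, apoptosis and pyroptosis 8 and 8 of 23, and mitochondrially encoded genes 0 and 1 of 11. Camera adjusted p-values for these lists ran from 0.107 (oxidative phosphorylation) to 0.992, and the counts adjusted over the list alone from 1 (mitochondrially encoded genes) to 30 (oxidative phosphorylation). The signs of median, mean and camera differed for Wnt targets (0.09, 0.12, down), immediate early genes (-0.01, 0.10, up), growth factors (-0.24, 0.24, down), autophagy (-0.01, 0.01, up) and apoptosis (-0.01, -0.07, up), and for FOXO targets the mean was 0.15 with a camera direction of down.

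Among markers of other cell types in EMT6, Cd68 fell from 19.4 ± 2.07 to 7.39 ± 0.937 FPKM, with 1 higher and 2 lower of 3 tested leukocyte markers. Of 2 endothelial and fibroblast markers 1 was called lower, Pdgfra, from 5.55 ± 0.321 to 4.83 ± 0.481 FPKM, a call lost on leaving out a library, as was that of Cd14 (10.9 ± 1.02 to 8.81 ± 0.59 FPKM). Both tested histone genes were called higher. Control replicate 1 held more Malat1, 450 CPM against 189 and 213 in the other controls and 158 to 200 in KO. In all, edgeR called 7224 of 12890 tested genes in EMT6 (56.0%, and 7805 at an unadjusted p under 0.05), 3591 higher and 3633 lower, and 6954 without control replicate 1. KO and control libraries did not overlap for 62.6% of the genes, against 10% by chance, and 586 genes were higher and 706 lower by at least 1 on the log2 scale.

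**Figure D2:**
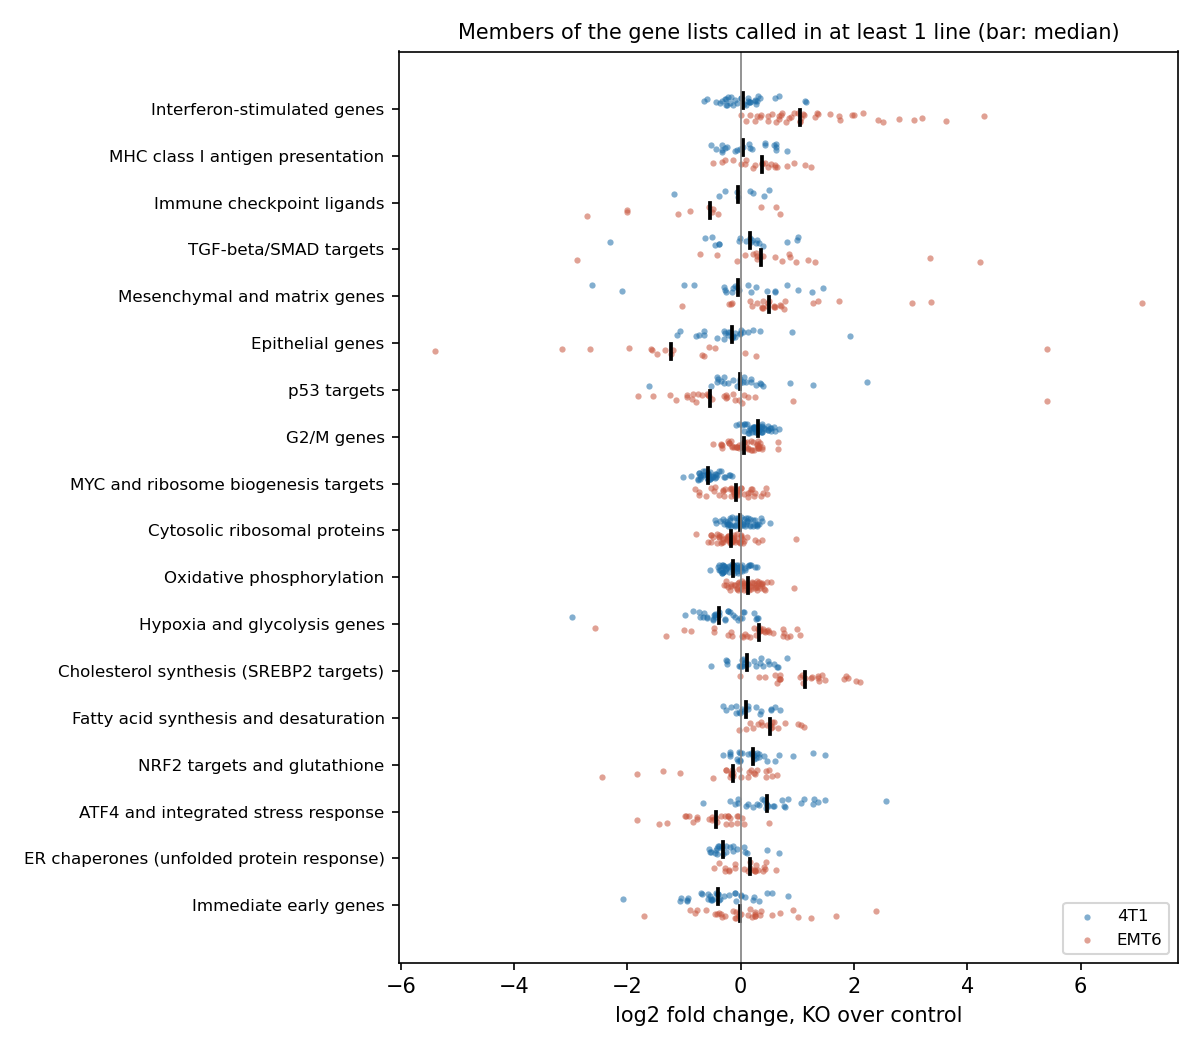
Log2 fold change, KO over control, of the tested members of the 18 gene lists called in at least 1 line, with 4T1 in blue, EMT6 in red and a black bar at each median. Ribosome biogenesis targets have a median of -0.57 in 4T1 and cholesterol synthesis genes a median of 1.14 in EMT6.

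Genes shifted by chromosome in both lines. In 4T1, camera called 13 chromosomes. Genes of chromosome X had a median of 0.30, with 215 of 375 higher and 33 lower (camera adjusted p = 8.62e-10), those of chromosome 12 a median of -0.21, with 70 higher and 236 lower (camera adjusted p = 2.71e-05), and those of chromosome 3 a median of 0.15, with 277 higher and 87 lower (camera adjusted p = 0.000172). In EMT6, camera also called 13. Genes of chromosome 14 had a median of -0.27, with 43 higher and 230 lower (camera adjusted p = 8.64e-07), those of chromosome 11 a median of -0.23, with 130 higher and 523 lower (camera adjusted p = 1.41e-06), and those of chromosome X a median of 0.27, with 197 higher and 45 lower (camera adjusted p = 3.57e-06). With an estimated correlation 12 chromosomes were called in 4T1 and 13 in EMT6, and X was at camera adjusted p = 0.0035 in 4T1 and 0.00857 in EMT6. Without the low-count filter, 5 chromosomes were called in 4T1 and 6 in EMT6.

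**Figure D3:**
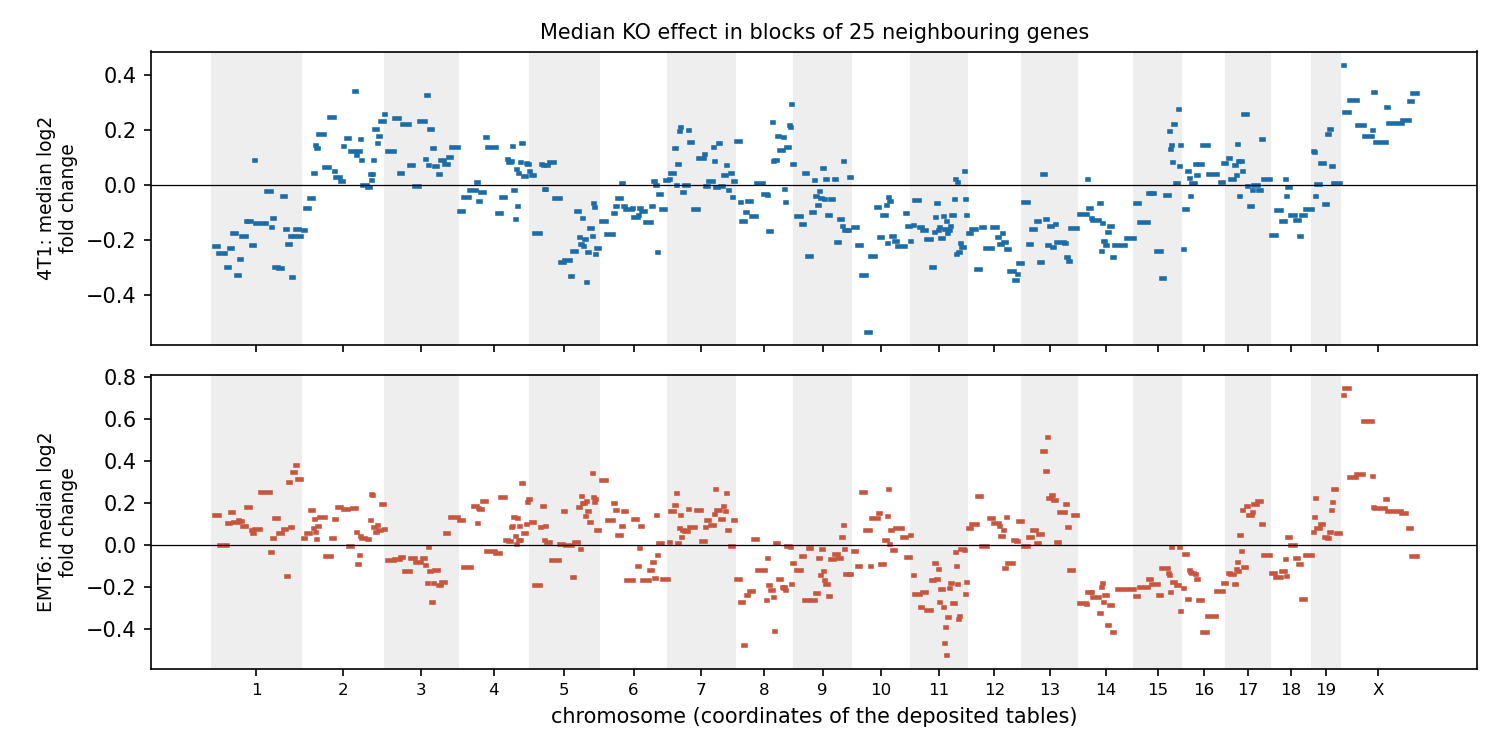
Median log2 fold change, KO over control, in blocks of 25 neighbouring genes along chromosomes 1 to 19 and X, with 4T1 above and EMT6 below. Some chromosomes lie to one side as a whole, such as X in 4T1 (median 0.30) and 14 in EMT6 (median -0.27). Others change along their length, such as X in EMT6, from 0.71 in its first block to -0.05 in its last.

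Compared directly, the lines differed in many of these groups. The ATF4 and stress response list, higher in the KO of 4T1 and lower in that of EMT6, had a median difference of log2 changes (EMT6 minus 4T1) of -0.93 (camera adjusted p = 5.86e-06, adjusted p = 0.451 with an estimated correlation). In KO against control, Slc7a11 was 2.82-fold higher in 4T1 and 3.53-fold lower in EMT6. Interferon-stimulated genes differed by 0.91 (camera adjusted p = 3.75e-06), and that call held with an estimated correlation (adjusted p = 0.0491). Cxcl5, a neutrophil-attracting chemokine, rose from 113 ± 3.84 to 159 ± 5.35 FPKM in 4T1 and fell from 312 ± 29.4 to 26.6 ± 1.57 FPKM in EMT6 (difference of log2 changes -3.98, edgeR adjusted p = 7.99e-20). Of the other genes called in opposite directions with the lowest interaction p, the protease inhibitor Slpi moved by 0.57 ± 0.10 in 4T1 and -2.76 ± 0.06 in EMT6, annexin Anxa8 by 0.60 ± 0.12 and -4.89 ± 0.13, and the TGF-beta co-receptor Cd109 by 1.27 ± 0.08 and -1.25 ± 0.05. In KO against control, xanthine dehydrogenase (Xdh) was 3.49-fold higher in 4T1 and 1.86-fold lower in EMT6, and Als2cl 1.16-fold higher and 4.59-fold lower.

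Camera called 12 list differences. Cholesterol synthesis (0.89, camera adjusted p = 3.75e-06), MYC and ribosome biogenesis (0.46, camera adjusted p = 9.74e-06), ER chaperones (0.36, camera adjusted p = 0.00386) and fatty acid synthesis (0.37, camera adjusted p = 0.0106) had higher log2 changes in EMT6 than in 4T1. So did oxidative phosphorylation (0.22, camera adjusted p = 0.00522) and hypoxia and glycolysis (0.49, camera adjusted p = 0.0144). G2/M genes (-0.27, camera adjusted p = 0.00213), epithelial genes (-0.68, camera adjusted p = 0.00386), ribosomal proteins (-0.22, camera adjusted p = 0.0352) and YAP/TEAD targets (-0.27, camera adjusted p = 0.0389) had lower log2 changes in EMT6. With an estimated correlation these 10 were not called, at adjusted p = 0.436 for epithelial genes and YAP/TEAD targets, 0.451 for cholesterol, ribosome biogenesis, G2/M, ER chaperones and fatty acid synthesis, 0.498 for oxidative phosphorylation, 0.556 for ribosomal proteins and 0.596 for hypoxia and glycolysis. The difference was not called for MHC class I (camera adjusted p = 0.0654), TGF-beta targets and mesenchymal genes (camera adjusted p = 0.0888 for each), p53 targets (camera adjusted p = 0.0881), NRF2 targets (camera adjusted p = 0.0796), checkpoint ligands (camera adjusted p = 0.252) or immediate early genes (camera adjusted p = 0.0577), which had been called in 1 line each.

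Some genes were called in the same direction in both lines, though for Cd300lb, Xlr, Abcg2, Btc and Nedd4 the size of the change differed (edgeR, adjusted p = 0.0465, 0.0286, 0.0106, 0.0351 and 1.14e-13). Higher in both were Amigo2 (3.66 ± 0.14 in 4T1 and 2.79 ± 0.33 in EMT6), Cd300lb (2.60 ± 0.31 and 1.59 ± 0.30), and X-linked Xlr (1.79 ± 0.16 and 2.53 ± 0.23), whose family has close copies. The leptin receptor Lepr was 3.23-fold and 4.58-fold higher. Clca3a1 went from 2 to 8 counts per library to 44 to 69 in 4T1 and from 0 to 2 to 11 to 16 in EMT6. Lower in both besides Nedd4 were the drug efflux pump Abcg2 (-3.58 ± 0.36 and -2.44 ± 0.12), the thyroid hormone deiodinase Dio2 (-2.80 ± 0.40 and -3.80 ± 0.31), Msx3 (-2.16 ± 0.29 and -2.71 ± 0.28), envoplakin (Evpl, -1.70 ± 0.23 and -2.47 ± 0.36) and the EGF receptor ligand Btc (-1.56 ± 0.10 and -1.95 ± 0.11).

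**Figure D4:**
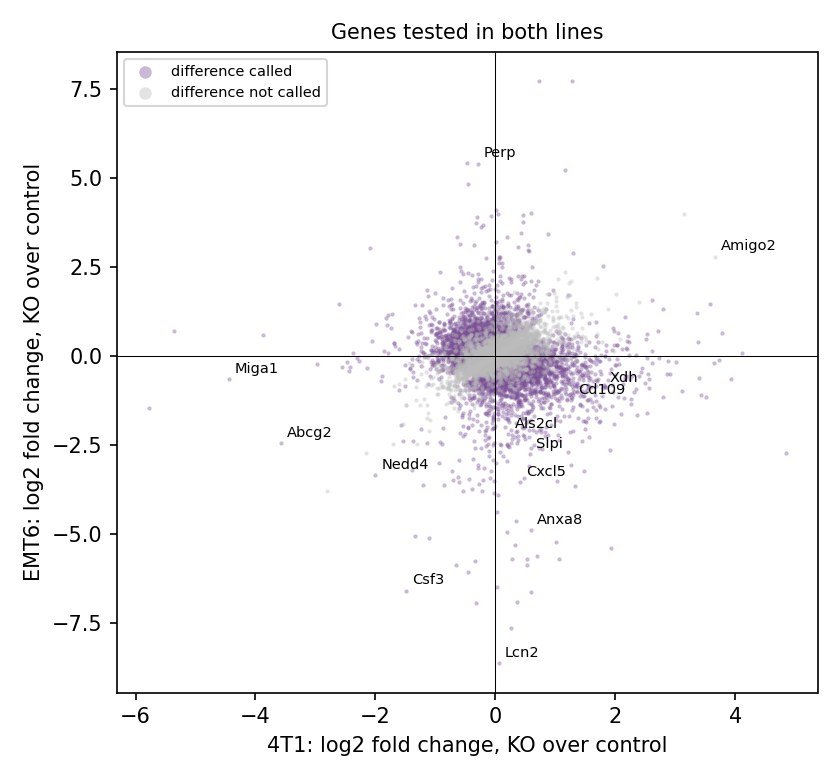
Log2 fold change, KO over control, in 4T1 (x axis) and in EMT6 (y axis) for the 12006 genes tested in both lines, with genes whose change differs between the lines in purple and 13 genes labelled. Nedd4 lies low in both, and Slpi and Anxa8 lie to the right of 0 and far below it.

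Across the 12006 genes tested in both lines, edgeR called a difference of the KO effect for 7197 (59.9%, and 7645 at an unadjusted p under 0.05). The KO effect here is the difference between a line's KO and control cells, whatever its source. Pearson's r of the log2 changes across genes was -0.068 and Spearman's rho -0.11, and genes are not independent replicates. That r was -0.136 with DESeq2, -0.106 without EMT6 control replicate 2 and -0.0439 without EMT6 control replicate 1. Called higher in both were 847 genes and lower in both 943, against 923 and 1007 for independent calls, while 1131 were higher in 4T1 and lower in EMT6 (920 for independent calls, Fisher's exact test, 1-sided p = 1.42e-21) and 1223 the reverse (1010, Fisher's exact test, 1-sided p = 6.29e-21). Among genes that moved by at least 1 on the log2 scale, 38 were higher in both (15.8 for independent calls, Fisher's exact test, 1-sided p = 4.86e-07), 28 lower in both (6.25, Fisher's exact test, 1-sided p = 1.76e-11), 80 higher in 4T1 and lower in EMT6 (19.2, Fisher's exact test, 1-sided p = 6.93e-29) and 13 the reverse (5.16, Fisher's exact test, 1-sided p = 0.002). Of the 4 counts at that size, all exceeded those of independent calls. Fisher's exact test also treats genes as independent, while genes of a chromosome shifted together in each line. Some chromosomes shifted in opposite directions in the lines, such as chromosome 1, and others alike, such as X. The p-values of overlap do not allow for this, and its part in the counts was not tested.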

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

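In this part, the tests of the chromosome shifts, of the number of genes with a count and of the Nedd4 reads left in KO were chosen only after the results were seen. The counts of other splits were set before. The test of an even background was set before its own outcome was seen, but for a pattern found in the results.

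The KO effect differed between the lines by a direct test, in edgeR's fit of all 12 libraries, for 7197 of 12006 genes. In a sample of 100 splits of the libraries within the lines, only the real one gave as many genes. The highest of the other splits gave 2956. Regrouping a line removes its KO effect, so the splits cannot tell whether equal effects in both lines would give this count. They do not exclude chance for a difference between the lines. Nor can the interaction test tell a line's own response to Nedd4 loss from other differences between its KO and control cells. The loss itself was unequal, with 26.3% of the control level of Nedd4 left in 4T1 and 9.89% in EMT6. The 14 other splits with calls, 1288 to 2956 genes, all kept the real grouping of 1 line, and the 85 splits that kept neither gave 0 in edgeR, with 38 to 228 at an unadjusted p under 0.05. In 4T1 the real split gave 7589 called genes and was the 1 of 10 splits with as many, and the highest other gave 0 in edgeR (43 to 156 at an unadjusted p under 0.05). In EMT6 the real split gave 7224 and was the 1 of 10 with as many, and the highest other gave 0 in edgeR (40 to 156 at an unadjusted p under 0.05). With 10 splits, a share under 0.05 cannot be reached. The other splits also put KO and control libraries into the same group, so the KO effect widens the spread within groups. Their 0 calls, and those of the 85 splits, therefore do not show what libraries without a KO effect would give.

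The difference of log2 changes, EMT6 minus 4T1, was -1.35 for Nedd4, -3.98 for Cxcl5, -3.35 for Slpi, -2.54 for Cd109, -2.44 for Als2cl, -5.51 for Anxa8 and -2.71 for Xdh, and 83 other named genes also had a called difference. Among lists, the median difference was 0.91 for interferon-stimulated genes, 0.89 for cholesterol synthesis, 0.49 for hypoxia and glycolysis, 0.46 for MYC and ribosome biogenesis targets, 0.37 for fatty acid synthesis, 0.36 for ER chaperones and 0.22 for oxidative phosphorylation. It was -0.93 for ATF4 and stress response genes, -0.68 for epithelial genes, -0.27 for YAP/TEAD targets, -0.27 for G2/M genes and -0.22 for ribosomal proteins.

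The chromosome-wide shifts were set against GC or length bias, low-abundance genes and a copy-number difference of segments. Removing a trend on GC content and gene length left 12 of the 13 called chromosomes in 4T1 and 13 of 13 in EMT6, and keeping only genes with a mean of at least 5 FPKM left 13 in each line, so neither accounts for the shifts as a whole, though without the low-count filter 5 and 6 were called. Within chromosomes, block medians of 25 genes, 3 blocks apart and with the GC and length trend removed, correlated at 0.0563 in 4T1 and 0.132 in EMT6, above the 95th percentile of within-chromosome shuffles (0.0447 and 0.0381), which is consistent with a copy-number difference of large segments, narrowly in 4T1, though neighbouring genes regulated together were not tested as a cause. For shifts of whole chromosomes no test here tells copy number from regulation, no DNA was measured, and a change that arose while the KO cells were made coincides with the knockout. After centring each chromosome 11 lists in 4T1 and 13 in EMT6 were called and only the 4T1 NRF2 list lost its call, so most list calls do not rest on the shifts, while their part in single gene changes stays open.

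The 4T1 KO libraries held more genes with a count and more genes higher than lower at a log2 change of at least 1. Library size does not account for the first, since after thinning to equal totals the lowest KO library still had 1366 more genes with a count than the highest control. Counts over 1769 olfactory and vomeronasal receptor genes, as a measure of background, were 2.26 times higher in CPM in KO, and sense-intronic genes stood at 76.3 to 87.4 against 37.2 to 53.8 CPM, which is consistent with background from genomic DNA or unspliced nuclear RNA. In EMT6 KO receptor counts were also higher (1.51 times) without more genes with a count after thinning (17539 to 18012 against 17563 to 18833) and with less Neat1 (28.2 to 36.1 against 66.8 to 138 CPM), so receptor counts alone do not go with more genes. An even background over exons of that size reached at least 50% of the gain in 0% of the 756 higher genes. Its median was 0.234% of the gain, so an even background does not explain the 756. Background that is uneven over genes, such as nuclear RNA, or concentrated in introns or in overlapping genes was not tested. An effect of the knockout stays open.

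Nedd4 reads left in KO were set against a paralog and admixed control cells. Nedd4l reached at most 13.1% of the Nedd4 level in a 4T1 KO library and 27.8% in an EMT6 KO library, too little to supply the Nedd4 reads. Control cells or control reads mixed in would hold every control-expressed gene at or above Nedd4's share. However, 9 genes in 4T1 and 18 in EMT6 had an upper counting bound below it. As observed shares, not bounds, Miga1 reached at most 5.12% of its control level in a 4T1 KO library, and Lcn2 0.306% in an EMT6 one. This test replaced a first bound, at least 10 genes below 13.1% (4T1) or 4.94% (EMT6) in every KO library, which 7 genes in 4T1 and 18 in EMT6 met. The tests argue against both explanations as the whole cause, though for admixture in 4T1 only the replacing test does so. RNA still made from edited or unedited Nedd4 alleles stays open as the reads' source, untested.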

How the results depend on the processing

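Thinned libraries, edgeR on genes with a mean of at least 5 FPKM, chromosome centring and the GC and length correction were chosen only after the results were seen. No gene called in a line was called in the opposite direction where an alternative tested genes (centring, the GC and length correction and protein-coding genes only did not), and 0 tested results changed direction. The share of 4T1 calls that were higher, 49.1%, crossed 50% to 61.2% with total counts only, 58.2% with limma on log2(FPKM + 1) and 62.3% with unfiltered FPKM. Of the values answering a comparison, 312 kept their side or size, 25 became weaker or smaller, 2 stronger and 1 moved, and of the other results (named genes, lists and shares) 5415, 285, 47 and 3. Leaving out 1 library at a time gave 6853 to 7293 called genes in 4T1 and 6242 to 7040 in EMT6, Nedd4 at -2.03 to -1.98 and -3.36 to -3.32, 8 to 11 and 10 to 12 lists, 10 to 14 and 11 to 14 chromosomes, 6818 to 7211 differences between lines and a Pearson r of -0.106 to -0.0439. Calls of 16 named genes in a line were lost so, in 4T1 those of Arrdc1, Atf4, Dsp, Id2 and Nos2, and in EMT6 those of Arrdc3, Cd14, Cdc25b, Crim1, Hspa5, Manf, Ndfip2, Ndufs1, Ocln, Pdgfra and Pfkl.

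With fewer genes tested, counts fell. At a mean of at least 5 FPKM, limma called 4666 genes in 4T1 (2458 higher, 2208 lower) and 4729 in EMT6 (2282 lower), and edgeR called 4900 (2445 and 2455) and 4810 (2389 and 2421). Requiring a log2 change of at least 1 left 1018 (756 and 262) in 4T1, 1292 (586 and 706) in EMT6, 38 higher and 28 lower in both, and 1733 differences. Unfiltered FPKM gave 2224 lower genes in 4T1, where scaling by total counts shifted genes by 0.08. Without the low-count filter 5 chromosomes in 4T1 and 6 in EMT6 were called, and DESeq2 gave a Pearson r of -0.136; the cause was not tested. Camera with an estimated correlation called 0 lists in 4T1 and 0 in EMT6 (4 and 3 at an unadjusted p under 0.05), and fry 23 and 19. Replicate numbers did not pair the libraries, since deviations of KO and control libraries with the same number correlated at -0.13 to 0.0091 across genes. With replicate as a block, 7853 and 6890 genes, 9 and 11 lists, 13 and 12 chromosomes and 6997 differences were called, with a Pearson r of -0.0893. Quantile scaling of FPKM, planned for tables without counts, was not run. Genes with few counts, such as Inmt, Il36g and Bmyc, are limited by depth.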

Other observations

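The germline-gene and pathway tests in this part, and the genes named in it, were chosen only after the results were seen.

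The fixed list of chemokines and cytokines was not called, with 8 higher and 10 lower of 23 in 4T1 (camera adjusted p = 0.757) and 5 higher and 9 lower of 21 in EMT6 (camera adjusted p = 0.267), and the genes here were picked for their values. In EMT6, edgeR called lower the inflammatory cytokine Il6 (-3.07 ± 0.30, SE), the neutrophil chemokines Cxcl2 (-3.22 ± 0.16, from 27.6 to 2.96 FPKM) and Cxcl1 (-2.39 ± 0.09, from 95.4 to 18.2 FPKM), the pattern-recognition protein Ptx3 (from 273 to 46.1 FPKM) and Il33 (-1.93 ± 0.09). The interferon-inducible chemokine Cxcl10 rose by 3.34 ± 0.26 and Ccl5 by 1.67 ± 0.22 in EMT6. In 4T1, Ccl5 fell by 1.12 ± 0.12, the epithelial cytokine Tslp from 37.9 to 12.8 FPKM, the interleukin subunit Il23a from 17.5 to 6.36 FPKM and Csf3 from 143 to 54 FPKM, while the macrophage growth factor Csf1 rose from 29.1 to 63.0 FPKM. The interaction test of edgeR called the difference between lines for Cxcl1 (adjusted p = 8.45e-11) and Ccl5 (adjusted p = 5.26e-10), and not for Il23a (adjusted p = 0.297).

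Single genes of EGF receptor ligands, proteases and matrix changed, picked for their values, while in 4T1 the fixed lists of growth factors and receptors (camera adjusted p = 0.757) and of mesenchymal and matrix genes (camera adjusted p = 0.983) were not called. Areg fell from 72.6 to 32.1 FPKM in 4T1 and from 139.9 to 53.8 FPKM in EMT6, Tgfa by 0.74 ± 0.05 and by 1.29 ± 0.10, and Hbegf by 0.88 ± 0.05 and by 0.28 ± 0.08. Thbs1, a matrix glycoprotein that activates TGF-beta, rose from 45.7 to 110 FPKM in 4T1 and from 152 to 330 FPKM in EMT6, and the protease Adamts1 rose by 0.85 ± 0.05 and 1.32 ± 0.12. In 4T1 the matrix metalloproteases Mmp10, Mmp9 and Mmp3 fell by 2.62 ± 0.10, 2.09 ± 0.12 and 0.99 ± 0.07, urokinase (Plau) fell from 96.2 to 41.3 FPKM, hyaluronan synthase Has2 from 37.8 to 14.9 FPKM and the collagen receptor subunit Itga2 from 47.0 to 15.3 FPKM. In EMT6, Mmp9 rose by 3.02 ± 0.38 at a low level (0.09 to 0.73 FPKM).

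The pathway annotation in the deposited tables was tested with camera over 330 pathways in 4T1 and 333 in EMT6, and with an estimated correlation none was called (smallest adjusted p = 0.873 and 0.998). In 4T1, 56 of 82 ribosome biogenesis genes were lower and 6 higher (camera adjusted p = 7.96e-06), 99 of 183 spliceosome genes lower and 10 higher (camera adjusted p = 6.84e-05), and 28 of 52 proteasome genes lower and 0 higher (camera adjusted p = 0.0164). In EMT6, 12 of 14 genes of chondroitin and dermatan sulfate synthesis were higher and 0 lower, and 13 of 18 genes of steroid biosynthesis higher and 2 lower (camera adjusted p = 0.00396 for each). Genes of xenobiotic metabolism by cytochrome P450 were lower in EMT6, 23 of 37 with 5 higher (camera adjusted p = 0.00667), with glutathione transferase Gsta4 down from 536 to 254 FPKM.

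Rhox5 and Xlr, X-linked genes of the reproductive tract and the germ line, raised the hypothesis that germline genes silenced by DNA methylation rose as a group. On a list of 36 such genes, without those 2, 6 had at least 10 counts in 4T1 and 2 of them were called higher, Sycp1 (1.67 ± 0.24) and Brdt, which had no control count. For the members in 4T1, limma's camera gave adjusted p = 0.255, with 1 set tested. In EMT6, 2 members had at least 10 counts, too few for the set test, and Sycp1 and Brdt were not called. The counts of these genes are too few to decide in either line.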
